A study of Mus musculus with 23 samples.

How the data were processed

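The series measured liver RNA of male and female mice, WT or KO for P2ry13, on 23 arrays. RNA was amplified to biotin-labelled cRNA and stained with streptavidin-phycoerythrin, per the labels' protocols. The deposited values are a linear-scale intensity per probe set, made with RMA per the submitters' processing notes; the version, the array description and the settings of RMA are not given in the sources used here. The deposited table holds 38385 probe sets with values from 4.12 to 29673.9, and its array medians lie between 19.5 and 21.1, close enough that no further scaling was applied in the tests reported first. The values were converted to log2 before any test. Groups and replicate numbers were taken from the sample titles: 6 female WT, 6 female KO, 6 male KO and 5 male WT, the last numbered 2 to 6. The design text gives 6 mice per group and 5 for male WT, and no batch, litter, cage or strain is given in the sources used here.

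Probe sets were named from the platform annotation of the repository. Of the 38385, 24478 had 1 gene symbol, 65 had several and 13842 are unnamed here; the named ones cover 19147 symbols, and 3958 genes had more than 1 probe set. By Entrez ID, 24237 of the 24478 were found in a RefSeq gene table of assembly GRCm38.p6 and 241 were not. That table was used for chromosomes and gene order only, as the array names no assembly, and no positions are printed. No gene was named from a probe set with several symbols.

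A linear model with 1 mean per group was fitted to all 23 arrays for each probe set with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 19 residual and 7.61 prior degrees of freedom), so that the 4 groups share an estimate of the spread. Its contrasts were KO minus WT in females, in males and as the average of both sexes with equal weights, the difference of the KO effects (females minus males), females minus males averaged over genotypes, and a moderated F test over the groups. P-values were adjusted by Benjamini-Hochberg over all probe sets, and an adjusted p under 0.05 counts as passing. Errors beside log2 fold changes are standard errors from limma with its moderated spread, and errors beside group means are SDs. Gene lists, 26 in number, were tested with camera on the brightest probe set of each gene, with the preset correlation of 0.01, adjusted over the lists of a comparison; camera with an estimated correlation and fry were run beside it. The location of called genes was compared with that of all placed genes by Fisher's exact test, one-sided. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

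Before the data were examined, the comparisons and their limma and list tests, the alternatives other than the one named below, the lists and the rule for naming genes were fixed. The test of the location of called genes was chosen after the calls had been seen. The rule names P2ry13 and a fixed set of lipid genes whatever their result, the 10 genes with the highest and the 10 with the lowest log2 fold change among those passing in each KO against WT comparison and between the sexes, 5 and 5 for the difference of the KO effects, and up to 4 members with the smallest p in each list with a passing member, or up to 2 in a list with none. Only probe sets with a single symbol that is no clone or predicted-gene name count, with the smallest-p probe set for each gene. Not every gene the rule allows is printed, and some of the fixed lipid genes are not reported here.

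The alternatives were a filter on dim probe sets (19192 above the median of 4.35 stayed), quantile normalization, equal array medians, array weights, an intensity trend with robust variance, the replicate number as a block, a minimum change of 20%, the design text's plain test before and after adjustment, only the compared groups in the fit, additive sex and genotype terms for the average, and leaving out each array in turn. For lists they were an estimated correlation, fry and the mean of a gene's probe sets. Leaving out the named probe sets placed on chromosome 3 was added after the data were seen. For each comparison 100 splits of the arrays, the real one included, were drawn and fitted the same way. The test of male RNA in the female WT samples was first run on 1 probe set per Y-linked gene, which left out a probe set of Uty and argued against male RNA; it is reported on all 4, with their mean set against the mean of their needs. Set against the smallest need among the 4, as first written, their mean plus 2 standard errors would not lie below it. Folds given as "at least" set the highest value of a Y-linked probe set in females, 3.69, as the floor of each array.

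The fit was tested on simulated data made with the spread of the real arrays. For KO against WT in females over 38385 probe sets, it recovered 8 of 50 probe sets changed by 0.3 on the log2 scale (16%), 37 of 50 changed by 0.5 (74%), 49 of 50 changed by 1 (98%) and 50 of 50 changed by 2. It called 150 in all, 6 of them unchanged, and 0 in males, where nothing was changed. The sterol synthesis genes were also raised by 0.2 in the simulated female KO arrays. Noise was drawn independently for each probe set, with no sex difference and no correlation between genes. These counts therefore do not give the rate of false calls in the real data.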

Results

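RNA from the livers of 23 mice was measured on whole-transcriptome arrays, with 1 array per animal as the design text describes it: 6 female wild-type (WT), 6 female knockout (KO), 5 male WT and 6 male KO. The KO mice lacked P2ry13, also called GPR86, a receptor for ADP of the P2Y family. The study asked which liver transcripts differ when this gene is ablated. Each array gave an intensity for 38385 probe sets, and the male WT arrays carry the replicate numbers 2 to 6. Array medians lay between 19.5 and 21.1 in linear intensity units, and the correlation between any pair of arrays over all probe sets lay between 0.983 and 0.995. In the most similar pair of arrays, 0.581% of the values were identical. Probe sets of Y-linked genes, read on the 12 female arrays, show where signal without transcript lay for 4 probe sets: 2.53 to 3.69, with a median of 2.95. In what follows, background means values up to the top of this range. The level can be higher at other probe sets: Xist, a female marker used below, read 4.14 to 5.22 in the male arrays. The number of arrays per group limits the precision of every value given here.

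The knocked-out gene was measured first, in every array. P2ry13 read 6.36, 6.42, 6.09, 6.40, 6.03 and 6.32 (log2 intensity) in female WT replicates 1 to 6, and 5.21, 5.22, 5.16, 5.06, 5.09 and 5.18 in female KO replicates 1 to 6. It read 6.34, 5.83, 5.80, 6.09 and 5.92 in male WT replicates 2 to 6, and 5.17, 5.34, 5.32, 5.07, 5.16 and 5.11 in male KO replicates 1 to 6. Every KO array lay below every WT array. P2ry13 fell by 1.12 on the log2 scale in females (SE 0.09, 2.17-fold lower, limma, adjusted p = 6.07e-09) and by 0.80 in males (SE 0.09, 1.74-fold lower, limma, adjusted p = 2.12e-05). In a plain analysis of variance of the male arrays, without the spread shared by limma, its adjusted p was 0.187. The remaining KO signal, 5.15 ± 0.06 (SD, n = 6) in females and 5.19 ± 0.11 (SD, n = 6) in males, stayed above the level of the Y-linked probe sets in females. Both means lay within the 4.14 to 5.22 that Xist read in the male arrays, so they do not show that transcript remained. Where the probe set lies relative to the deleted part of the gene is not given in the sources used here, so the size of the drop does not measure how much of the transcript was lost. The sex labels were checked with Xist, the RNA that silences an X chromosome, and with the Y-linked genes Eif2s3y and Kdm5d. Xist lay between 8.42 and 9.78 in the female arrays and between 4.14 and 5.22 in the male arrays. Eif2s3y lay between 2.72 and 3.45 in the female arrays and between 8.23 and 8.91 in the male arrays.

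**Figure D1:**
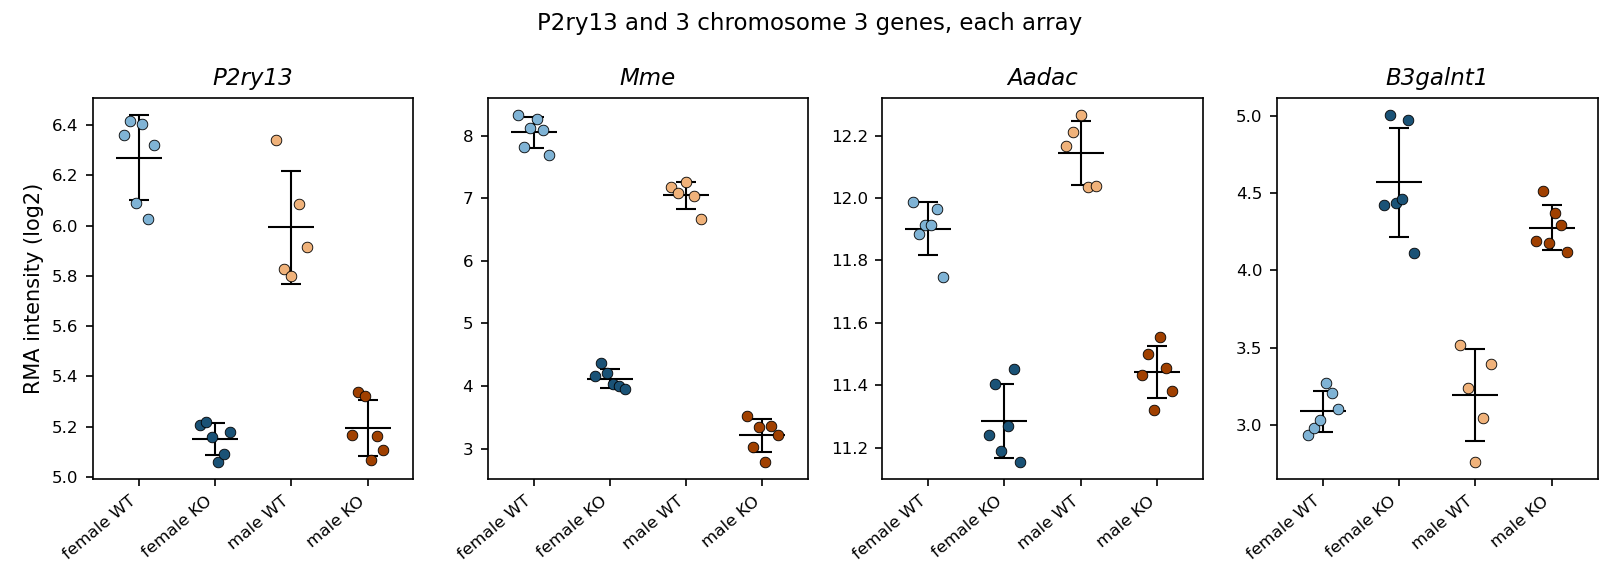
Log2 RMA intensity of P2ry13, Mme, Aadac and B3galnt1 in each of the 23 arrays (points) by group (horizontal axis), with the group mean and SD as bars. For each of the 4 genes no KO array overlaps a WT array of the same sex; P2ry13 reads 5.15 in female KO against 6.27 in female WT on average.

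In female livers, the sulfotransferases of hydroxysteroids and bile acids rose most: Sult2a2 went from 3.86 ± 0.21 in WT to 8.86 ± 1.52 in KO (log2, SD, n = 6 each), 32.1-fold higher, and Sult2a1 from 5.94 ± 0.99 to 9.38 ± 0.36, 10.9-fold higher. Hao2, a peroxisomal hydroxyacid oxidase, was 6.22-fold higher. In the other direction, Hsd3b5, a male-biased member of the hydroxysteroid dehydrogenase family, went from 9.16 ± 0.98 to 5.43 ± 0.63, 13.3-fold lower, and Mme, the membrane peptidase neprilysin, from 8.05 ± 0.25 to 4.12 ± 0.16, 15.3-fold lower. All 6 KO arrays lay beyond all 6 WT arrays for each of these 5 genes (limma, adjusted p = 6.07e-09 for Sult2a2, 1.27e-08 for Sult2a1, 1.14e-05 for Hao2, 1.7e-08 for Hsd3b5 and 1.69e-18 for Mme). The WT level of Sult2a2 lies close to the range of the Y-linked probe sets, with replicate 2 inside it at 3.52, so the size of its rise is uncertain.

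Further genes rose in females. Asic5, an ion channel of the acid-sensing family, rose by 1.97 on the log2 scale (SE 0.32, limma, adjusted p = 0.00455), and B3galnt1, a glycosyltransferase of globoside synthesis, by 1.48 (SE 0.13, limma, adjusted p = 4.62e-08). B3galnt1 in female WT lay in the range of the Y-linked probe sets, so its size is only a bound: set against the top of that range, it was at least 1.84-fold higher. Jade1, a subunit of a histone acetyltransferase complex, rose by 0.84, Ppm1l, a protein phosphatase of the endoplasmic reticulum, by 0.66, and Trim2, a ubiquitin ligase, by 0.56 (limma, adjusted p = 2.28e-06, 0.00142 and 0.00136). Other probe sets of Jade1 (-0.12) and Ppm1l (0.26 and -0.05) did not show these rises. All 6 KO arrays were above all WT arrays for these 5 genes.

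Besides Mme and Hsd3b5, a smaller set fell in females. The succinate receptor gene Sucnr1 changed by -1.05 (SE 0.19, limma, adjusted p = 0.0228), Hsd3b3 by -1.40 (SE 0.27, limma, adjusted p = 0.0286), and Aadac, a microsomal deacetylase of lipids and drugs, by -0.62 (SE 0.07, limma, adjusted p = 3.42e-06). Cyp2d9, a male-biased steroid hydroxylase, changed by -0.80 (SE 0.10), from 10.77 to 9.98 (limma, adjusted p = 2.42e-05). Smaller falls were seen for Acad9, a mitochondrial acyl-CoA dehydrogenase (-0.53), Mccc1, a carboxylase of leucine breakdown (-0.50), and Scnm1, a splicing factor (-0.47; limma, adjusted p = 0.00155, 0.0252 and 0.0429). Of the 6 KO arrays, 6 lay below all WT arrays for Aadac, Cyp2d9, Acad9 and Mccc1, and 5 did for Sucnr1, Hsd3b3 and Scnm1. The Hsd3b3 call ended without female KO replicate 1, 2, 4 or 6 or female WT replicate 1, 2, 3, 4 or 6, at an adjusted p of up to 0.115 (limma). The Sucnr1 call ended without female KO replicate 1, 3, 4 or 6 or female WT replicate 1, 2 or 5, at up to 0.0998. The Mccc1 call ended without female KO replicate 1, 3 or 4 or female WT replicate 1, 2, 3, 4 or 6, at up to 0.11. The Scnm1 call stood without female KO replicate 5 or female WT replicate 5 and ended without any other female array, at up to 0.192. With only the female arrays in the limma fit, Sucnr1, Mccc1 and Scnm1 did not pass (adjusted p = 0.0719, 0.0614 and 0.273).

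Counted over all probe sets, limma with Benjamini-Hochberg adjustment called 21 of 38385 in females, 9 higher and 12 lower in KO, and 2253 had an unadjusted p under 0.05 where chance alone gives 1919. The 21 stand for 18 named genes and 2 probe sets without a gene name here. Of the 18 genes, 15 lie on chromosome 3, as P2ry13 does, by the gene table of assembly GRCm38.p6; Sult2a1, Sult2a2 and Cyp2d9 lie on other chromosomes. Probe sets can share signal between close paralogs, so the values of Sult2a1 against Sult2a2, and of the Hsd3b genes against each other, are uncertain. An intensity trend with robust variance ended the female calls of Asic5, Hsd3b3 and Sucnr1 (limma, adjusted p = 0.0823, 0.204 and 0.137). In a plain analysis of variance of the female arrays, without the spread shared by limma, the adjusted p was 0.0504 for Sult2a2 and Sult2a1, 0.0545 for Hsd3b5, 0.392 for Hao2, 0.261 for Cyp2d9, 0.197 for Asic5, 0.131 for Trim2, 0.151 for Acad9, 0.683 for Hsd3b3, 0.895 for Sucnr1, 0.421 for Mccc1 and 0.9 for Scnm1, so none of these 12 passed there.

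Genes with a known sex bias in mouse liver moved together in female KO. Of 17 measured male-biased genes, Hsd3b5 and Cyp2d9 fell, 15 did not pass over all probe sets, and 14 had negative log2 fold changes, with a median of -0.26. Adjusted over the list alone, 8 fell. Examples that did not pass are the complement gene C6 (-0.48, limma, adjusted p = 0.154), and Susd4, a complement inhibitor (-0.64, limma, adjusted p = 0.285). Of 17 measured female-biased genes, Sult2a1 rose and 16 did not pass over all probe sets; all 17 had positive values, with a median of 0.42. Adjusted over the list alone, 7 rose. Cyp3a16, a female-biased monooxygenase, read 2.61 higher (limma, adjusted p = 0.0549), and Cyp2g1 read 0.73 higher (limma, adjusted p = 0.579). The camera test gave an adjusted p of 2.49e-14 for the male-biased list (down) and 5.99e-14 for the female-biased list (up). Both calls held with an estimated correlation (camera, adjusted p = 0.00354 and 0.000905), and fry gave adjusted p = 0.000656 and 0.000231. These are the only camera calls of a KO against WT comparison, within a sex or averaged, that held with an estimated correlation.

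In female KO, 18 of 19 measured genes of sterol synthesis had positive values, with a median of 0.22. None of the 19 rose over all probe sets, and 0 rose adjusted over the list alone; Mvd, an enzyme of the mevalonate pathway, read 0.65 higher (limma, adjusted p = 0.735) and Insig1, a brake on sterol-regulated transcription, 0.34 higher (limma, adjusted p = 0.789). The list was called by camera at an adjusted p of 7.22e-09, but not with an estimated correlation (camera, adjusted p = 0.26 with an estimated correlation). For the circadian clock, 14 of 18 measured genes were positive and none rose, over all probe sets or adjusted over the list alone; Hlf, a clock output factor, read 0.32 higher and the repressor Cry2 0.26 higher (limma, adjusted p = 0.645 and 0.818). This list had an adjusted p of 0.0131 by camera, and an adjusted p = 0.26 with an estimated correlation. Its call ended without female KO replicate 2 or female WT replicate 3, at an adjusted p of up to 0.111 (camera). Of 24 measured genes fixed as neighbours of P2ry13, Mme, Aadac and Sucnr1 fell, over all probe sets and as 3 genes adjusted over the list alone. The median of these 24 genes was 0.05 and their mean -0.19, and camera pointed down without passing (camera, adjusted p = 0.155), while fry, which tests the list on its own, passed (fry, adjusted p = 0.00131).

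**Figure D2:**
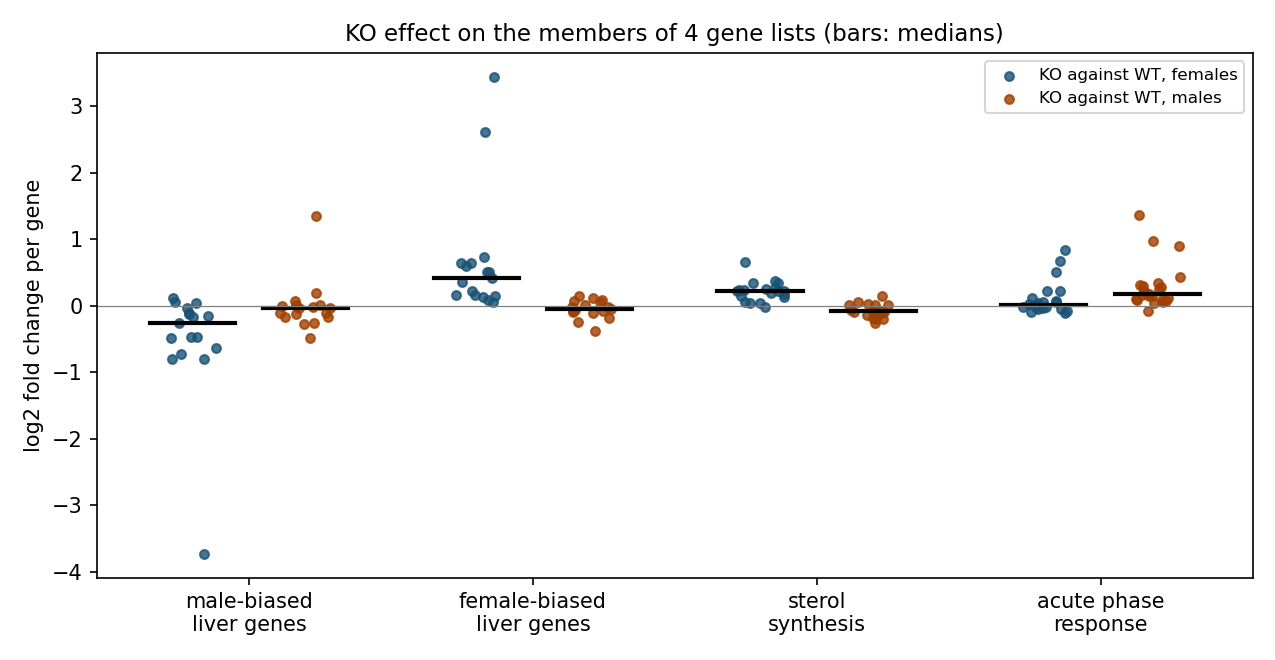
Log2 fold change of KO against WT for each measured member of 4 gene lists (points; horizontal axis: lists; blue females, orange males), with black bars at the medians. In females the medians are -0.26 for male-biased, 0.42 for female-biased and 0.22 for sterol synthesis genes; in males the acute phase median is 0.18.

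In male livers, Mme fell most among named genes, from 7.04 to 3.21 (at least 10.2-fold lower, limma, adjusted p = 1.15e-17), and Asic5 rose most, from 5.84 ± 1.13 (n = 5) to 8.46 ± 0.26 (n = 6), 6.18-fold higher (limma, adjusted p = 0.000183). B3galnt1 rose by 1.09 (SE 0.14), Jade1 by 0.55 (SE 0.09) and Ppm1l by 0.58 (limma, adjusted p = 0.000111, 0.012 and 0.0303). Mme in male KO and B3galnt1 in male WT lay in the range of the Y-linked probe sets in females; set against the top of that range, the rise of B3galnt1 was at least 0.58 on the log2 scale. Another probe set of Jade1 read -0.06. Baz1a, a subunit of chromatin remodelling complexes on chromosome 12, rose by 0.63 (SE 0.12, limma, adjusted p = 0.0395). Sucnr1 changed by -1.30 (SE 0.20), Aadac by -0.70 (SE 0.07) and Hsd3b6, a further hydroxysteroid dehydrogenase, by -0.92 (SE 0.16; limma, adjusted p = 0.00369, 1.81e-06 and 0.0192). All 6 KO arrays lay beyond all 5 WT arrays for Mme, Asic5, B3galnt1, Ppm1l, Baz1a, Sucnr1 and Aadac, 5 of 6 did for Jade1 and 4 of 6 for Hsd3b6.

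The male comparison called 12 of 38385 probe sets (limma, Benjamini-Hochberg), 6 higher and 6 lower, with 2355 at an unadjusted p under 0.05 against 1919 by chance. They stand for 10 named genes, 9 of them on chromosome 3, and 2 probe sets without a gene name here. Male WT replicate 6 lay at 7.85 for Asic5, 10.11 for Hsd3b3 and 7.37 for Hsd3b6, near the male KO means of 8.46, 10.12 and 7.35 and apart from the other male WT arrays. Without this array the count was 21, the Asic5 change was 3.13 and the Hsd3b6 change -1.15 (limma, adjusted p = 5.06e-09 and 4.62e-06). The Hsd3b6 call ended without male KO replicate 1 or 3 or male WT replicate 2, 3, 4 or 5 (limma, adjusted p up to 0.121). The Ppm1l call ended without male KO replicate 1, 3 or 4 or male WT replicate 2, 3 or 4 (up to 0.128), the Jade1 call without male WT replicate 2 or 3 (up to 0.0827), and the Baz1a call without male KO replicate 1, 2, 3 or 6 or male WT replicate 2, 4, 5 or 6 (up to 0.192). With only the male arrays in the limma fit, Ppm1l, Jade1 and Hsd3b6 did not pass (adjusted p = 0.269, 0.25 and 0.134). Without the spread shared by limma, in a plain analysis of variance, the adjusted p was 0.598 for Asic5 and Baz1a, 0.187 for B3galnt1, 0.394 for Sucnr1 and 0.82 for Ppm1l, Jade1 and Hsd3b6, and none of them passed.

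**Figure D3:**
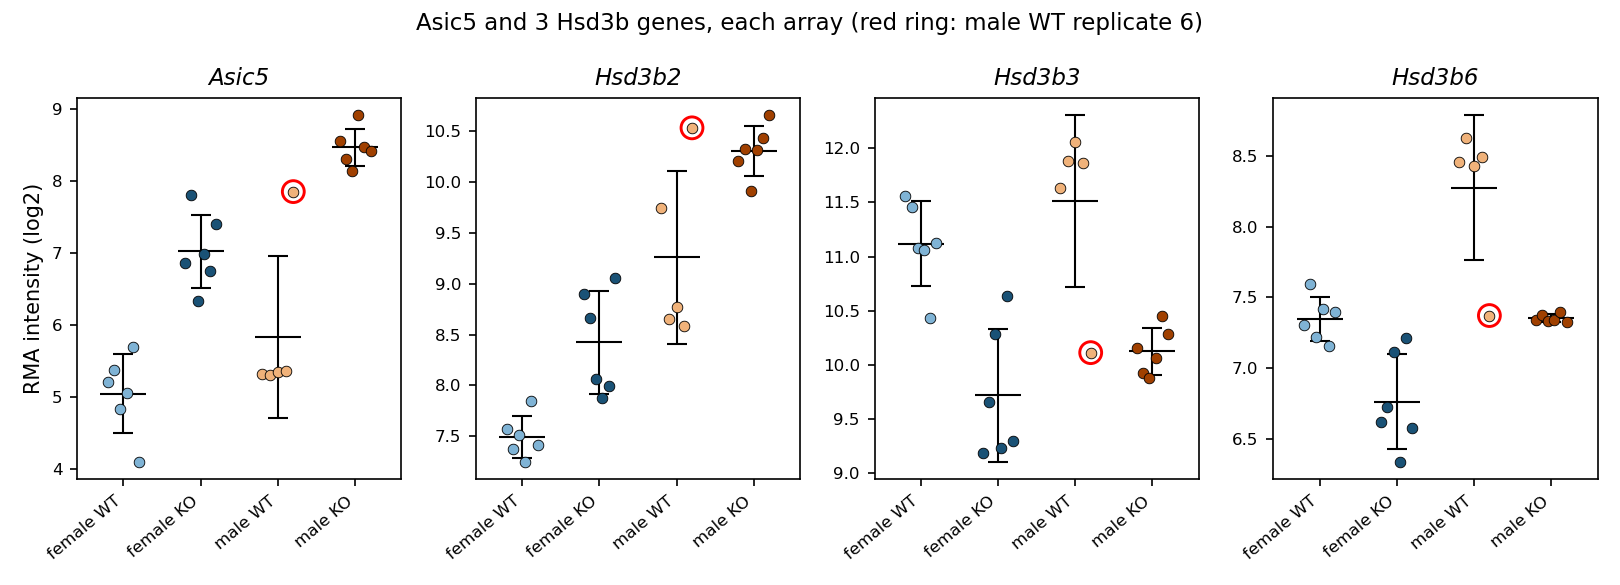
Log2 RMA intensity of Asic5, Hsd3b2, Hsd3b3 and Hsd3b6 in each array (points) by group, with the group mean and SD; a red ring marks male WT replicate 6. For Asic5 that array reads 7.85, while the other male WT arrays lie between 5.30 and 5.36.

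Among male gene lists, the acute phase response, liver proteins made in inflammation, lay higher in KO: 22 of 23 measured genes were positive, with a median of 0.18. None rose over all probe sets and 6 rose adjusted over the list alone. Itih4, an inhibitor heavy chain, read 0.35 higher, Itih3 0.31 higher, the serum amyloid gene Saa2 1.36 higher, and Steap4, a metalloreductase, 0.43 higher (limma, adjusted p = 0.158, 0.424, 0.406 and 0.524). The list had an adjusted p of 1.3e-11 by camera, and an adjusted p = 0.16 with an estimated correlation. Of the 24 neighbours of P2ry13, Mme, Aadac and Sucnr1 fell in males too, over all probe sets and adjusted over the list alone. Camera called these neighbours lower at an adjusted p of 0.00123, and not with an estimated correlation (camera, adjusted p = 0.16 with an estimated correlation); fry gave an adjusted p of 0.000114. Sex-biased and sterol lists were not called in males (camera, adjusted p = 0.86 for male-biased, 0.601 for female-biased and 0.103 for sterol synthesis genes). The number of male lists called, 2, rose to 4 without male KO replicate 1, male WT replicate 5 or male WT replicate 6, to 5 without male KO replicate 3, and to 6 without male KO replicate 4 or male WT replicate 2.

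Averaged over the female and male effects, the largest fall was that of Mme and the largest rise that both sexes showed was that of Asic5. Mme (-3.88), Sucnr1 (-1.18), Aadac (-0.66), Asic5 (2.30), B3galnt1 (1.28), Jade1 (0.70) and Ppm1l (0.62) passed (limma, adjusted p = 5.23e-22, 1.85e-05, 1.12e-09, 1.41e-06, 1.12e-09, 1.85e-07 and 1.68e-05). For Mme and B3galnt1 the averages take in groups in the range of the Y-linked probe sets, and the bounds are at least 12.5-fold lower and at least 1.66-fold higher. The hydroxysteroid dehydrogenases Hsd3b3 (-1.39) and Hsd3b6 (-0.75) fell, while Hsd3b2 rose by 0.99 (limma, adjusted p = 0.000225, 0.000822 and 0.0133); another probe set of Hsd3b2 read 0.04. Mccc1 (-0.49) and Acad9 (-0.46) also fell (limma, adjusted p = 0.000192 and 8.33e-05). Near the threshold were Snx27, an endosomal sorting protein (0.42), the pattern receptor gene Tlr2 (0.41) and Fabp2, a fatty acid carrier (-0.43; limma, adjusted p = 0.0489, 0.0451 and 0.0493).

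The average called 31 probe sets (limma, Benjamini-Hochberg), 14 higher and 17 lower, which stand for 24 named genes, 21 of them on chromosome 3, and 6 probe sets without a gene name here; 2651 had an unadjusted p under 0.05 against 1919 by chance. An intensity trend with robust variance ended the Hsd3b2 and Hao2 calls (limma, adjusted p = 0.124 and 0.0818), and another probe set of Snx27 read 0.05. The Snx27 call stood only without female WT replicate 4, female WT replicate 5, male KO replicate 5 or male WT replicate 6, the Tlr2 call only without female KO replicate 2, male WT replicate 2 or male WT replicate 6, and the Fabp2 call only without female KO replicate 2, female KO replicate 3, male KO replicate 4 or male WT replicate 6. For every other array left out these 3 genes did not pass (limma, adjusted p up to 0.131, 0.112 and 0.132). The calls of Sult2a2, Sult2a1, Hao2, Hsd3b5 and Cyp2d9 in the average came with changes in females, and none of these genes passed in males. With the sexes pooled in a plain analysis of variance, without limma, 11 of the genes called in the average did not pass: Sult2a2, Sult2a1, Hsd3b2 and Hsd3b5 at an adjusted p of 0.936, Hao2 at 0.944, Cyp2d9 at 0.981, Hsd3b6 at 0.882, Tlr2 at 0.368, and Sucnr1, Snx27 and Fabp2 at 0.348.

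With the brightest probe set per gene, the sexes shared 7 called genes: P2ry13, Mme, Aadac, Sucnr1, Asic5, B3galnt1 and Jade1; Ppm1l was called in both by another probe set. Of the 7, 3 were higher in both sexes where independent lists would share 0.00146, 4 were lower in both where 0.00261 would be shared, and 0 went opposite ways. Across 19147 genes the female and male log2 fold changes had a Pearson r of 0.197 and a Spearman rho of 0.105; genes are not independent replicates. Over the 922 genes of chromosome 3 r was 0.629, and over the 17988 genes of other chromosomes 0.099. By rank the agreement on chromosome 3 was far weaker, with a Spearman rho of 0.209 there and 0.101 on other chromosomes. The r of 0.629 thus does not describe chromosome 3 genes in general.

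The genes called in the average, taken with the brightest probe set per gene and without P2ry13, were 22, of which 19 lie on chromosome 3. Chromosome 3 holds 4.88% of the 18910 placed genes (Fisher's exact test, one-sided, p = 1.3e-22). The same count was 13 of 16 in females and 7 of 8 in males (Fisher's exact test, one-sided, p = 3.91e-15 and 4.88e-09). These tests take adjacent paralogs, such as the Hsd3b genes, as separate genes. Of the 19 genes, 8 were higher and 11 lower in KO. They spread from 102 genes before P2ry13 to 531 genes after it in the order of the assembly, with 3 before and 16 after, where 211 measured genes lie before and 710 after. At an unadjusted p under 0.05 chromosome 3 had 11.9% of its genes, more than the rest of the genome (Fisher's exact test, Benjamini-Hochberg over chromosomes, adjusted p = 6.13e-07), and no other chromosome passed, the lowest adjusted p being 0.719.

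**Figure D4:**
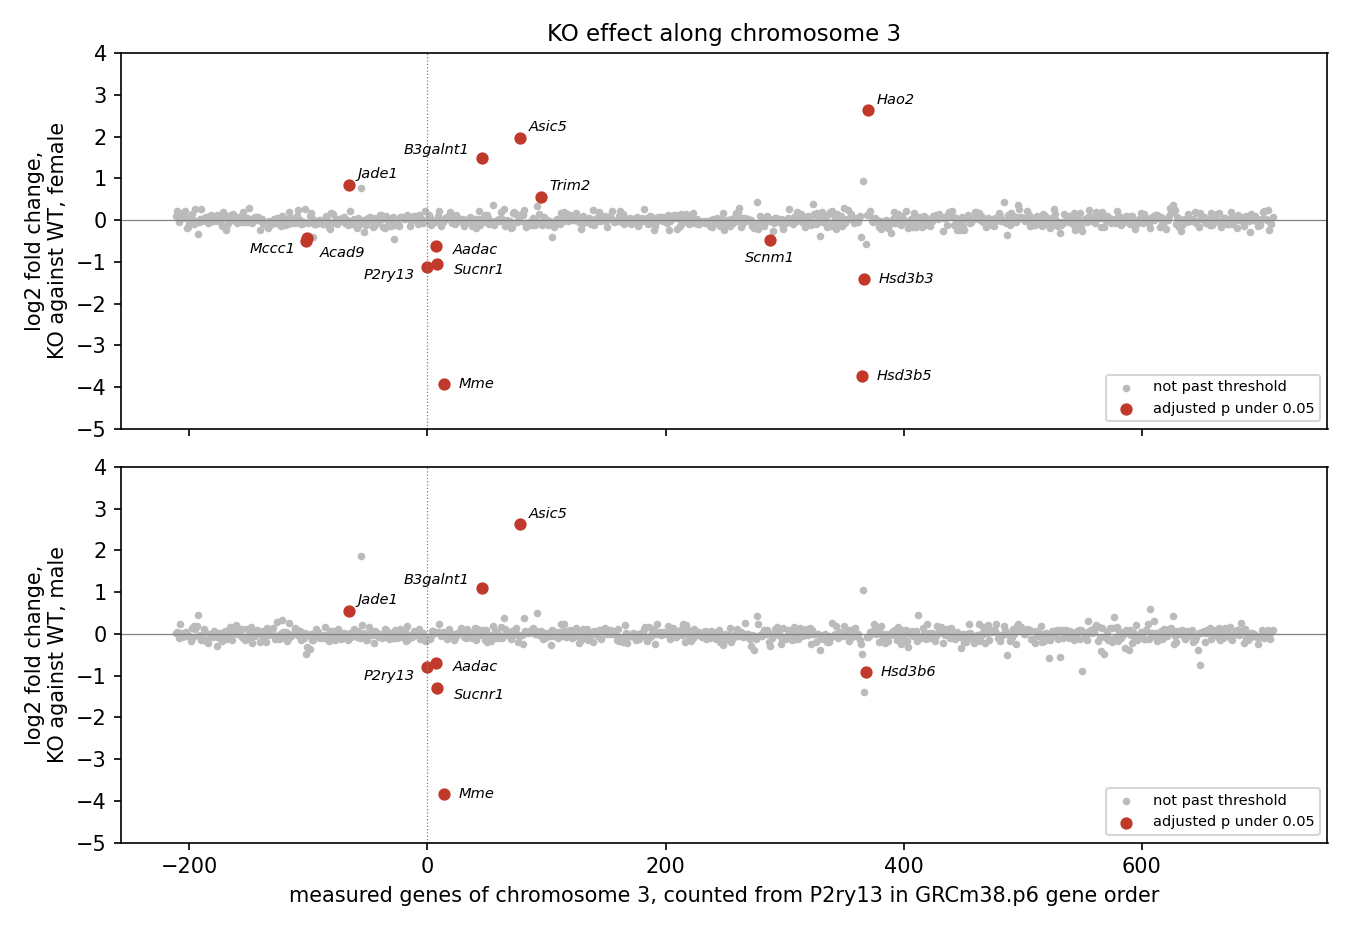
Log2 fold change of KO against WT in females (top) and males (bottom) for the measured genes of chromosome 3, placed by gene order from P2ry13 (dotted line); red points have an adjusted p under 0.05. Called genes lie on both sides of P2ry13 and include the Hsd3b genes more than 300 genes away.

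In the average of both sexes, 8 of 26 lists were called by camera and none with an estimated correlation. Acute phase response (adjusted p = 6.55e-07 by camera, 0.264 with an estimated correlation), female-biased genes (6.3e-06 and 0.0667), circadian clock (0.0153 and 0.264), lipoprotein and HDL metabolism (0.0434 and 0.286), sterol synthesis (0.0434 and 0.799) and Kupffer cell markers (0.0434 and 0.799) lay higher. Male-biased genes (camera, adjusted p = 3.04e-07, and 0.0667 with an estimated correlation) and neighbours of P2ry13 (camera, adjusted p = 0.0108, and 0.232 with an estimated correlation) lay lower. Fry passed for the neighbours (adjusted p = 6.19e-06), the male-biased and the female-biased genes (adjusted p = 0.0159 each), and for no other list. Kupffer cells are the resident macrophages of the liver; their markers Fcna, a ficolin, and Cd5l, a secreted scavenger protein, read 0.18 and 0.22 higher (limma, adjusted p = 0.518 and 0.521), none of the 16 markers rose over all probe sets, and 3 rose adjusted over the list alone. In lipoprotein and HDL metabolism, where 16 of 24 measured genes were positive, none rose over all probe sets or adjusted over the list alone. The number of lists called, 8, dropped to 5 without female KO replicate 4, male KO replicate 6, male WT replicate 2 or male WT replicate 5, and to 4 without female WT replicate 3.

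The genes of cholesterol and lipoprotein handling reported here, named before the data were examined because P2ry13 has been studied in hepatic HDL uptake, did not pass in either sex. Apob, the protein of very-low-density lipoprotein, read -0.41 in females and 0.15 in males (limma, adjusted p = 0.915 and 0.977). Scarb1, the HDL receptor, read 0.18 and 0.19 (limma, adjusted p = 0.854 and 0.812), and Abca1, the cholesterol efflux pump, 0.04 and 0.19 (limma, adjusted p = 0.982 and 0.818). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, read 0.53 and -0.75 (limma, adjusted p = 0.886 and 0.794). Srebf2, the regulator of sterol synthesis, read 0.17 and 0.02, and Mttp, the transfer protein of lipoprotein assembly, -0.02 and 0.08 (limma, adjusted p = 0.887, 0.99, 0.991 and 0.936).

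The test of a difference between the sexes' KO effects passed for 4 genes, and only Hsd3b5 was measured above the range of the Y-linked probe sets in both sexes. Its effects differed by -3.25 (SE 0.45, limma, adjusted p = 0.00116), with 12.51 in male WT and 12.03 in male KO. For Sult2a2, Sult2a1 and Hao2 both male groups lay in the range of the Y-linked probe sets in females, so a male change below that level could not be measured and the fitted differences do not settle that the effects differ. These were 4.92 for Sult2a2 (SE 0.56), with 2.57 in male WT and 2.65 in male KO, 3.50 for Sult2a1, with 2.75 and 2.69, and 2.72 for Hao2 (SE 0.44), with 2.80 and 2.71 (limma, adjusted p = 6.27e-05, 6.27e-05 and 0.0131). Of 38385 probe sets these were the only 4 to pass, and 1973 had an unadjusted p under 0.05 against 1919 by chance. An intensity trend with robust variance ended the Hao2 call (limma, adjusted p = 0.219), and a plain test without the spread shared by limma ended those of Hsd3b5 and Hao2 (adjusted p = 0.0749 and 0.227).

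**Figure D5:**
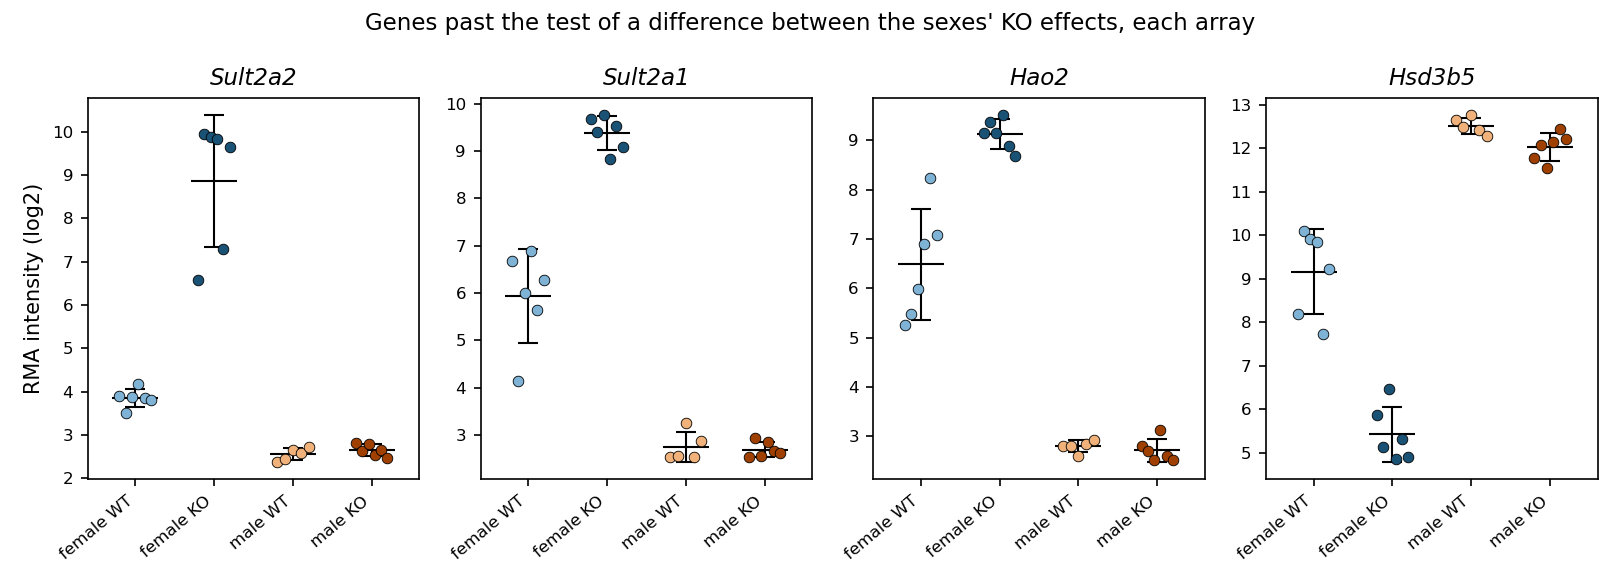
Log2 RMA intensity of Sult2a2, Sult2a1, Hao2 and Hsd3b5 in each array (points) by group, with the group mean and SD. All 6 female KO arrays lie beyond all 6 female WT arrays, while in males Sult2a2 averages 2.57 in WT and 2.65 in KO.

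Among lists, the difference between the sexes' effects was called by camera for 5. Female-biased genes (17 of 17 positive, adjusted p = 5.97e-10) and male-biased genes (14 of 17 negative, adjusted p = 1.85e-09) were also called with an estimated correlation (camera, adjusted p = 0.00529 and 0.0275; fry, adjusted p = 0.00416 and 0.0351). Of the female-biased genes 5 lay at background on every male array; without all genes that did, both lists were called by camera (adjusted p = 2.92e-05 and 3.41e-09) but not with an estimated correlation (camera, adjusted p = 0.0588 and 0.054). Sterol synthesis genes were positive in 19 of 19 (camera, adjusted p = 2.76e-09, and 0.293 with an estimated correlation). Acute phase genes were negative in 19 of 23 (camera, adjusted p = 2.06e-06, and 0.339 with an estimated correlation), and fatty acid oxidation genes positive in 16 of 24 (camera, adjusted p = 0.012, and 0.83 with an estimated correlation).

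Sex itself, averaged over both genotypes, gave the scale of a known difference. Cyp2b9, a female-specific monooxygenase, was at least 261-fold higher in females (log2 8.38, limma, adjusted p = 4.77e-32), and A1bg, a secreted plasma protein, 248-fold higher (limma, adjusted p = 4.65e-23). The sulfotransferase Sult3a1 (7.86), Cyp2b13 (5.98), Hao2 (5.05), Sult2a1 (4.93), the transporter Slc22a26 (4.46), Xist (4.35), the peroxisomal transporter Abcd2 (4.15) and the steroid hydroxylase Cyp17a1 (3.95) were the next highest in females. In males Eif2s3y (-5.73), Hsd3b5 (-4.97), the fatty acid elongase Elovl3 (-4.80), Nat8 (-3.88), the glucuronosyltransferase Ugt2b38 (-3.74), Kdm5d (-3.66), Cyp2d9 (-3.42), C6 (-3.35), the ferritin receptor Scara5 (-3.09) and Cyp7b1, an oxysterol hydroxylase (-2.78), were highest, with the sign taken as female minus male. Cyp2b9, Sult3a1, Hao2 and Sult2a1 in males and Eif2s3y and Kdm5d in females lay in the range of the Y-linked probe sets, so their sizes are bounds and their places in this order are uncertain: at least 131-fold for Sult3a1, 17.3-fold for Hao2, 15.6-fold for Sult2a1, 30.9-fold for Eif2s3y and 8.25-fold for Kdm5d. Some arrays lay in that range for Abcd2 in males and for Scara5 and Ugt2b38 in females, so these sizes are uncertain too. The averages take in the female KO effect: in WT alone Hao2 lay at 6.49 in females and 2.80 in males, Sult2a1 at 5.94 and 2.75, and Hsd3b5 at 9.16 and 12.51. Among these 20 genes the least certain was Ugt2b38 (limma, adjusted p = 7.62e-12). Of 38385 probe sets 4036 passed (limma, Benjamini-Hochberg), 2289 higher and 1747 lower in females. Of 17 male-biased genes 16 were lower in females, and of 17 female-biased genes 16 were higher (camera, adjusted p = 1.06e-46 and 1.61e-53; 1.91e-06 and 4.37e-08 with an estimated correlation); adjusted over the list alone all 17 passed in each.

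Any difference among the 4 groups was found for 2490 probe sets by the moderated F test (limma, Benjamini-Hochberg), and 7044 had an unadjusted p under 0.05. The design text reports 3471 transcripts by a one-way analysis of variance with an unadjusted threshold of 0.05 and a change beyond 20%. That test, run here over the 4 groups on the same values, gave 4454 probe sets, of which 1924 passed after Benjamini-Hochberg adjustment. Between KO and WT with the sexes pooled it gave 162 (12 after adjustment), in females 397 (7 after adjustment) and in males 582 (3 after adjustment), with 944 passing in either sex without adjustment.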

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

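The tests of male RNA, of genes at background in males, of chromosome 3 members, of left-out arrays with an estimated correlation, and of the order of genes in male WT replicate 6 were chosen after the results they address had been seen.

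A test of the difference between the female and male KO effects passed for Hsd3b5 (-3.25 on the log2 scale, limma, adjusted p = 0.00116). It also passed for Sult2a2 (4.92, limma, adjusted p = 6.27e-05), Sult2a1 (3.50, limma, adjusted p = 6.27e-05) and Hao2 (2.72, limma, adjusted p = 0.0131), but both male groups of these lay at background, where a male change could not be measured, so a difference is not settled for them. By camera the test passed for female-biased genes (adjusted p = 5.97e-10) and male-biased genes (adjusted p = 1.85e-09), which without the genes at background in males were not called with an estimated correlation (camera, adjusted p = 0.0588 and 0.054), and for sterol synthesis (adjusted p = 2.76e-09, and 0.293 with an estimated correlation), acute phase genes (adjusted p = 2.06e-06, and 0.339 with an estimated correlation) and fatty acid oxidation (adjusted p = 0.012, and 0.83 with an estimated correlation).

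In female KO the female-biased genes lay higher and the male-biased genes lower than in female WT. Male tissue or RNA in the female WT samples is argued against: the male-biased genes would need a median of 7.1% male RNA, which would raise 4 Y-linked probe sets by a mean of 0.879 and the female-biased genes in KO by a mean of 0.085, and these read 0.0579 (SE 0.0543) and 0.672 (SE 0.138), although 1 Uty probe set, with the smallest need of 0.164, read 0.251, while Eif2s3y, with a need of 2.21, read 0.0313. List members on chromosome 3 are not the whole cause, as both lists were still called without them (camera, adjusted p of at most 0.00327 with an estimated correlation), nor is a single array, as every left-out female array kept both calls (camera, adjusted p of at most 0.0166 with an estimated correlation, reached for male-biased genes without female WT replicate 4). Among 100 splits of the arrays, the real one included, 1 gave a camera p as small as the female-biased list's and 2 as small as the male-biased list's. The real camera p was 4.61e-15 and 9.58e-16, and the smallest among the other splits 5.29e-10 and 4.14e-17. Chance is thus argued against for each list taken alone, though another split gave a smaller p for the male-biased list. It is not excluded for the choice of these lists among 26. A hormonal or growth hormone-linked effect of losing P2ry13, strain differences elsewhere in the genome, and a batch or cage shared by a group all stay open as possible explanations, and none of these was tested.

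Some arrays stood apart from the rest of their group at a gene of the text. Over the 68 measured genes that the text names by its naming rule, 15 of 272 groups held such an array, and chance sets an array apart in about 1 in 20 groups, here 13.6. This set of genes was narrowed to those the text names after a count over all genes of the rule had been seen. Male WT replicate 6 had 4 of the 15. It read 7.85 for Asic5 (other male WT arrays 5.30 to 5.36), 10.11 for Hsd3b3 (11.63 to 12.05), 7.37 for Hsd3b6 (8.43 to 8.62) and 8.81 for Mvd (7.99 to 8.20).

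At several chromosome 3 genes male WT replicate 6 lay near the KO level. When this array is set against a male comparison made without it, 15 chromosome 3 genes are called, and it lies nearer to the KO mean at 9 of them, including Noct, Mrpl9, Slc16a1 and Abcd3, named here after their values were seen. The genes from Asic5 to Abcd3 in gene order form an unbroken run of 7, a length reached in a share of 0.0357 of 10000 shuffled gene orders, or of 0.121 with the adjacent Hsd3b paralogs, which may share signal, taken as 1 gene. P2ry13, Mme, Aadac, Sucnr1, B3galnt1 and Jade1 lie nearer to the WT mean. They are not an unbroken stretch: Noct lies between Jade1 and P2ry13, and Ppm1l between Mme and B3galnt1. Noct and Ppm1l read 0.61 and 0.56 of the way from the WT to the KO mean. KO-type DNA along part of chromosome 3 in that animal stays open, as the order of so few genes does not settle it. Female WT replicate 5 had 4 of 15 genes nearer to the KO mean with a longest run of 3 (share 0.108). With the Hsd3b genes taken as 1, its longest run was 2 (share 0.402). Female KO replicate 5 had 3 of 15, Sucnr1, Scnm1 and Hsd3b3, nearer to the WT mean with a longest run of 1. These runs decide nothing, and the sequence of the animals was not analysed here.

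In the other male WT arrays, Abcd2 read 4.48 in replicate 5 (3.73 to 3.92 in the others), Cyp2b13 read 4.32 in replicate 4 (5.40 to 5.59) and Slco1a1, a bile acid and steroid carrier, 11.29 in replicate 4 (10.98 to 11.07). In female WT replicate 4, Marco, a macrophage scavenger receptor, read 6.33 (4.73 to 5.26). In female KO arrays, C6 read 7.32 in replicate 1 (7.56 to 7.66), Cyp7a1 read 10.12 in replicate 3 (9.50 to 9.72), Snx27 read 7.46 in replicate 6 (6.95 to 7.06) and Xist read 9.78 in replicate 6 (8.91 to 9.18). In male KO arrays, Snx27 read 6.47 in replicate 5 (6.95 to 7.17), Tat, an enzyme of tyrosine breakdown, 12.43 in replicate 1 (12.85 to 13.03) and Xist 5.22 in replicate 1 (4.21 to 4.53).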

How the results depend on the processing

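Leaving out the named probe sets of chromosome 3 was the only alternative chosen after the data had been seen. No named gene or list that passed changed direction under any alternative run, though the balance of higher and lower calls did. The design text's plain test with its unadjusted threshold gave 397 probe sets in females, 582 in males, 162 with the sexes pooled, 1188 for the difference of the KO effects, 2345 between the sexes and 4454 for any difference, and after Benjamini-Hochberg adjustment 7, 3, 12, 2 and 1990 for the first 5; the counts without adjustment differ by construction, and the cause of the other differences was not tested. A minimum change of 20% left 2236 of the 4036 probe sets between the sexes, by construction, and all those called in the KO comparisons. Without the named probe sets of chromosome 3, the counts were 4 in females, 2 in males and 6 in the average. For the difference of the KO effects the count was 2. The correlation of female and male effects was 0.099 and the lists called in males 1, with fewer genes tested by construction. Probe sets with no chromosome known here stayed in that setting, so not all of these calls need lie outside chromosome 3. The male call of Baz1a ended in that setting and with equal array medians (limma, adjusted p = 0.151 and 0.0639). With an estimated correlation in place of the preset one, the only change in that run, 2 lists were called in females, 0 in males and 0 in the average. Fry called 3 in females, 1 in males and 3 in the average. The dim filter and quantile normalization each left 5 in the average, and array weights gave 5 in males. The cause of the changes under fry, the dim filter, quantile normalization and array weights was not tested. Equal array medians moved the split of calls to 11 higher and 9 lower in females (9 and 12 without it) and to 2573 and 1232 between the sexes (2289 and 1747 without it), while quantile normalization gave 2059 and 2011 there, so the excess of higher calls depends on the scaling, and the dim filter gave 20 higher and 18 lower in the average (14 and 17 without it). With the replicate number as a block the counts were 18 in females, 13 in males, 27 in the average, 4 for the difference of the KO effects, 3815 between the sexes and 2295 for any difference, P2ry13 changed by -0.96, the correlation was 0.209, and 4, 2 and 8 lists were called. The block moved the female split to 10 higher and 8 lower and ended the calls of Hsd3b3, Mccc1 and Scnm1 in females, Baz1a in males, and Snx27, Tlr2 and Fabp2 in the average. WT and KO arrays of the same number and sex showed little shared deviation. In females r ranged from -0.074 to 0.154, and 1 of 6 pairs correlated best with its own number. In males r ranged from -0.122 to 0.026, and 0 did. Between the sexes r ranged from -0.171 to 0.215. The numbers thus gave no clear sign of pairing, but this does not exclude a litter, cage or batch shared by arrays of the same number. With 1 array left out, the counts ranged from 16 to 29 in females, 9 to 21 in males (21 without male WT replicate 6), 23 to 39 in the average, 4 to 5 for the difference of the KO effects, 3491 to 4092 between the sexes and 2170 to 2475 for any difference. In the same settings P2ry13 ranged from -0.98 to -0.92, the correlation from 0.154 to 0.226, and the lists called from 3 to 6 in females, 2 to 6 in males and 4 to 9 in the average. Additive terms for sex and genotype ended the average's calls of Sult2a2, Sult2a1, Hao2, Cyp2d9, Tlr2 and Fabp2 (limma, adjusted p from 0.0577 to 0.293). Of 73 calls of named genes, 33 were lost in the adjusted plain test, 7 under the block, 6 with an intensity trend, 5 with equal array medians, 2 with quantile normalization, 1 with array weights and 0 of the 70 that the dim filter kept. For dim genes such as Hao2 and Sult2a2 in males, which lie at the level of Y-linked probe sets in females, a change below that level could not be seen.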

Other observations

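The tests of gene order, neighbours and chromosome share were chosen after the results they address had been seen; the splits of the arrays were planned before.

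Beyond the sex-biased enzymes, markers of several cell types other than hepatocytes and genes of lipid handling also differed by sex in these livers, and shares of cells were not measured. Of 16 measured Kupffer cell markers 13 were higher in females, among them Cd5l (0.42), Fcna (0.39) and Marco (0.83; limma, adjusted p = 8.96e-05, 2.61e-05 and 0.00924), and camera called the list at an adjusted p of 1.04e-13 (0.0179 with an estimated correlation). Of 18 interferon-stimulated genes 13 were higher in females (camera, adjusted p = 5.41e-14, and 0.0113 with an estimated correlation), and of 15 endothelial markers 7 (camera, adjusted p = 2.68e-06, and 0.0203 with an estimated correlation). Of 16 stellate cell and fibroblast markers 7 were higher, of 14 T and NK cell markers 5 and of 9 B and plasma cell markers 3 (camera, adjusted p = 0.000283, 0.00389 and 0.0474), and these lists were not called with an estimated correlation (camera, adjusted p = 0.0899, 0.09 and 0.185). Of 6 erythroid markers 3 were lower in females (camera, adjusted p = 0.00271, and 0.0311 with an estimated correlation). In lipoprotein and HDL metabolism 13 of 24 genes were higher in females, with Vldlr, a lipoprotein receptor, at 1.01 and Abcg5, a sterol exporter, at 0.66 (limma, adjusted p = 1.62e-09 and 2.3e-08; camera for the list, adjusted p = 9.62e-06, and 0.0113 with an estimated correlation).

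Nt5e, the ectonucleotidase that makes adenosine from AMP, was higher in females by 2.81 (limma, adjusted p = 9.65e-20); its KO effect was 0.25 in females and -0.51 in males, and neither passed (limma, adjusted p = 0.848 and 0.291). Of 21 genes of fatty acid and triglyceride synthesis 9 were higher and 2 lower in females, with Fasn, the fatty acid synthase, at 0.85 (limma, adjusted p = 2.21e-06); Gpam, which starts triglyceride synthesis, read -0.06 and the gluconeogenic Pck1 0.14, and neither passed (limma, adjusted p = 0.732 and 0.451). The synthesis list was called by camera at an adjusted p of 1.64e-05, but not with an estimated correlation (camera, adjusted p = 0.0899 with an estimated correlation). A probe set without a gene name here fell in KO by 3.75 in females and 3.33 in males on the log2 scale (limma, adjusted p = 1.2e-15 and 8.15e-14).

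Genes called between KO and WT lay mostly on chromosome 3, 19 of 22 in the average. A response that takes in genes wherever they lie is argued against as the whole cause (Fisher's exact test, one-sided, p = 1.3e-22), and so is an effect of the targeted sequence on adjacent genes, since 15 of the 19 lie more than 50 measured genes from P2ry13. The 19 genes lie nearer to P2ry13 than random chromosome 3 genes do, with a median distance of 102 genes against 249 (permutation test, one-sided, p = 0.00338, 100000 permutations). However, 7 of them lie more than 300 genes away, where 14.4% of the genes had an unadjusted p under 0.05, against 8% within 50 genes and 6.81% on other chromosomes. The 7 include Hsd3b5, Hsd3b2, Hsd3b3, Hsd3b6 and Hao2, which lie together, 365 to 370 genes away, and the Hsd3b paralogs may share signal. Counts and tests here take each gene on its own, so they do not count separate places on the chromosome. A stretch of another strain's chromosome 3 carried along with the targeted allele stays a hypothesis. Nearness to P2ry13 goes with it but would also follow from an effect on adjacent genes, and the shares did not fall with distance, so these values do not settle it. The strains of the KO and WT mice are not given in the sources used here. A share of receptor-dependent changes among these genes, and 3 genes on other chromosomes, stay open.

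For the counts of called probe sets, 1 of 100 splits, the real one, reached the real value in each comparison. With 100 splits, 1 of 100 is the lowest share that can be seen. Chance is thus argued against, but not excluded, for all of them but the difference of the KO effects. There the splits also take away the KO effect that the sexes share, so they cannot test a difference between the sexes, and the counts lie close together. The real counts and the highest of the other splits were 21 and 4 in females, 12 and 7 in males, 31 and 3 in the average, 4 and 3 for the difference of the KO effects, 4036 and 1 between the sexes, and 2490 and 42 for any difference. For the number of lists called by camera, chance cannot be excluded: 71 of 100 splits gave as many as the 4 in females (highest other 13), 73 as many as the 2 in males (highest other 10) and 12 as many as the 8 in the average (highest other 9). For the correlation of female and male effects chance cannot be excluded either, as 5 of 100 splits reached 0.197 (highest other 0.311). For sterol synthesis in females 8 of 100 splits gave a camera p as small as 8.33e-10 (smallest other 1.13e-16), and chance cannot be excluded. For acute phase genes in males 4 of 100 did (camera, real p 5.02e-13, smallest other 2.78e-15). Such a p was uncommon for this list taken alone, but other splits reached it and the list is 1 of 26, so chance is not excluded. The list was not called with an estimated correlation (camera, adjusted p = 0.16) or by fry (adjusted p = 0.0901).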
